A study of Mus musculus with 5 samples.

How the data were processed

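Single-cell RNA was measured in 15 mice, 3 in each of 5 groups. Per the labels' protocols, the 3 mice of a group were tagged with oligonucleotides and pooled in 1 lane, and 12000 cells were loaded per lane. In bone marrow, neutrophils were sorted apart and added back at 1 part to 10 parts of other cells. The deposited matrices hold UMI counts per gene and cell, without normalization, and every value checked was a whole number. Per the submitters' processing notes, reads were aligned to mm10 with Cell Ranger 2.1, whereas the bone marrow matrices name cellranger 7.0.1, per the file headers. Tag counts in the bone marrow matrices were left out of library sizes and tests. Of 32285 gene identifiers, 32158 (99.6%) matched the annotation used for transcript length and chromosome. Replicate numbers do not link lung mice to bone marrow mice.

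Cells were kept at 500 UMIs, 200 genes and at most 10% mitochondrially encoded UMIs. This removed 372 barcodes for UMIs or genes and 3275 for mitochondrial UMIs of 44950, and Scrublet in scanpy 1.11.5 (expected rate 0.06) removed 397 doublets. Lung myeloid, lung T cell and bone marrow libraries were clustered apart, without batch correction, on counts per 10000, 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2). A cluster took the name of the marker list with the highest score when at least 3 markers were found in 10% of its cells and the score reached 0.5, thresholds set after the data were opened. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9 were used.

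UMI counts were summed per mouse and class, since mice and not cells are the replicates. Classes with at least 20 cells in every mouse were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood F test). Lung fits used the 6 libraries compared, and bone marrow fits all 9, which share 1 estimate of the spread. P-values were adjusted over all genes tested with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Each adjusted p in the report is of this kind unless another tool is named. Gene lists, 28 fixed and 2 defined by gene name (ribosomal protein and mitochondrially encoded), were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, where at least 5 members were measured, adjusted over the lists of a comparison. Class shares were compared with exact two-sided permutation tests, whose smallest possible p is 0.10 with 3 mice against 3. Shares of cells with a UMI have exact binomial intervals. Cells were thinned to 2000 UMIs where depth mattered, and cells below that were left out.

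Genes named in the report are Il4ra, the 8 called genes with the largest change in each direction at 50 CPM or more in the higher group and with groups that do not overlap, and up to 3 members of each list with the smallest p. Predicted genes and variable receptor segments were left out of the largest changes. Genes outside this rule are said to be so. Groups, comparisons, lists, the naming rule and most alternatives were chosen before the data were examined. Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a replicate term, each mouse left out in turn, doublets kept, a stricter cell filter (1000 UMIs, 5% mitochondrial), resolutions 0.5 and 2.0, the 6 libraries compared alone, shares of all cells, and estimated correlation. DESeq2 gives no adjusted p to genes it filters, and these count as not called. RLE and DESeq2 factors shifted the median of all genes by at most 0.009 (log2).

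Precision was tested on simulated data with 200 changed genes per comparison. Of genes changed 2-fold, 52.2% to 74.6% were recovered, of those changed 4-fold 87.9% to 98.5%, and of those changed 1.5-fold 13.4% to 46.3%. Unchanged genes made up 7.98% to 10.2% of calls in lung and 0.719% to 5.60% in bone marrow. Lung neutrophil-like cells were planned but not tested.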

Results

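Single-cell transcriptomes were recorded for 15 mice in 5 groups of 3. Tumor-bearing lungs came from mice whose Ms4a3-Cre driver, active in granulocyte-monocyte progenitors, acts on floxed Il4ra (KO), and from mice with the driver alone (WT). Il4ra encodes the alpha chain of the IL-4 receptor. Each lung gave a myeloid library and a sorted T cell library. Bone marrow came from naive mice, from mice inoculated with KP tumor cells, and from mice given IL-4c (IL4c). The 21 libraries held 44950 barcodes, 19467 from lung and 25483 from bone marrow. Total UMIs per library ran from 3489443 to 8701039 in KO and from 5524837 to 12075535 in WT myeloid libraries. T cell libraries held 4175097 to 5424328 UMIs in KO and 5431350 to 10924631 in WT. Bone marrow libraries held 18675282 to 24507720 (naive), 25794516 to 30626565 (IL4c) and 35646807 to 40116396 UMIs (KP). Median UMIs per barcode were 5922 to 6504 in naive, 7173 to 7322 in IL4c and 11570.5 to 14107 in KP bone marrow, so KP depth was higher throughout.

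After filtering, 41273 cells remained, 7906 in myeloid, 10125 in T cell and 23242 in bone marrow libraries. Clusters were named by marker lists, and each name means only that the cluster resembled that type. Clusters without a name held 180 KO (5.16%) and 128 WT cells (2.90%) of the myeloid libraries, and 492 (12.7%) and 809 (13%) of the T cell libraries. In bone marrow they held 977 IL4c (10.6%), 105 KP (1.63%) and 348 naive cells (4.59%). Of the classes, 20 had at least 20 cells in every mouse and were tested, and 21 did not. Lung neutrophil-like cells were not tested, with 11, 15 and 23 cells in the KO mice and 3, 11 and 122 in the WT mice. The mice of 1 group shared a lane, so lane and group cannot be told apart, and each p-value below measures spread between mice within lanes. Values below are the CPM of a class's summed UMIs, mean ± SD over 3 mice, or log2 fold change ± SE. For a gene list the text gives how many measured members were called in each direction over all genes, how many changed when adjusted over the list alone, the median log2 fold change and the adjusted p of the list test.

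The targeted gene Il4ra (ENSMUSG00000030748) lies on chromosome 7 of mm10, plus strand, from 125552120 to 125579474. The lung comparison asks what its loss from progenitor-derived myeloid cells changes in tumor-bearing lung. Il4ra RNA did not differ detectably between KO and WT in any of 13 lung classes with a value (0 called by edgeR, lowest adjusted p = 0.325), with log2 fold changes from -1.0 to 0.36. Macrophage-like cells had 92.8 ± 5.12 CPM against 95.4 ± 11.1 CPM (log2 -0.03 ± 0.15, adjusted p = 0.997). Monocyte-like cells had 75.5 ± 12.2 CPM against 91.3 ± 32.5 CPM (log2 -0.35 ± 0.23, adjusted p = 0.754). The labels state a 3' kit, whose reads can lie outside the floxed part. Shared barcodes imply a smaller barcode pool in lung than in bone marrow, so the lung kit, and where its reads lie, stays uncertain. These values do not measure the deletion. In bone marrow, Il4ra rose in KP monocyte-like cells, 39.7 ± 10.6 CPM against 15.7 ± 4.94 CPM (log2 1.35 ± 0.25, adjusted p = 0.00527). It also rose in KP immature neutrophil-like cells, 17.6 ± 1.32 CPM against 10.8 ± 1.12 CPM (log2 0.70 ± 0.12, adjusted p = 0.00127), and was higher in 3 of 3 mice of both classes. In monocyte progenitor-like cells it was 18 ± 3.44 CPM against 11.2 ± 1.39 CPM (log2 0.69 ± 0.21, adjusted p = 0.0362). That call was lost with DESeq2, without KP mouse 1 or 2 or any naive mouse, and at both other cluster resolutions (adjusted p from 0.0650 to 0.339). KP neutrophil-like cells, 91.3 ± 12.3 CPM against 59.8 ± 10.8 CPM (log2 0.60 ± 0.23, adjusted p = 0.0962), and progenitor-like cells, 10.3 ± 0.557 CPM against 7.33 ± 0.975 CPM (log2 0.53 ± 0.30, adjusted p = 0.303), did not pass. In IL4c mice Il4ra rose in CD8 T-like cells, 108 ± 40.4 CPM against 47.2 ± 9.96 CPM (log2 1.12 ± 0.28, adjusted p = 0.0205), a call lost without IL4c mouse 2 (adjusted p = 0.145) or 3 (0.0972), naive mouse 2 (0.0829) or 3 (0.101), with DESeq2 (0.0575) and under the stricter cell filter (0.225). IL4c monocyte-like cells had 17.4 ± 3.76 CPM against 15.7 ± 4.94 CPM (log2 0.16 ± 0.28, adjusted p = 0.834).

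**Figure D1:**
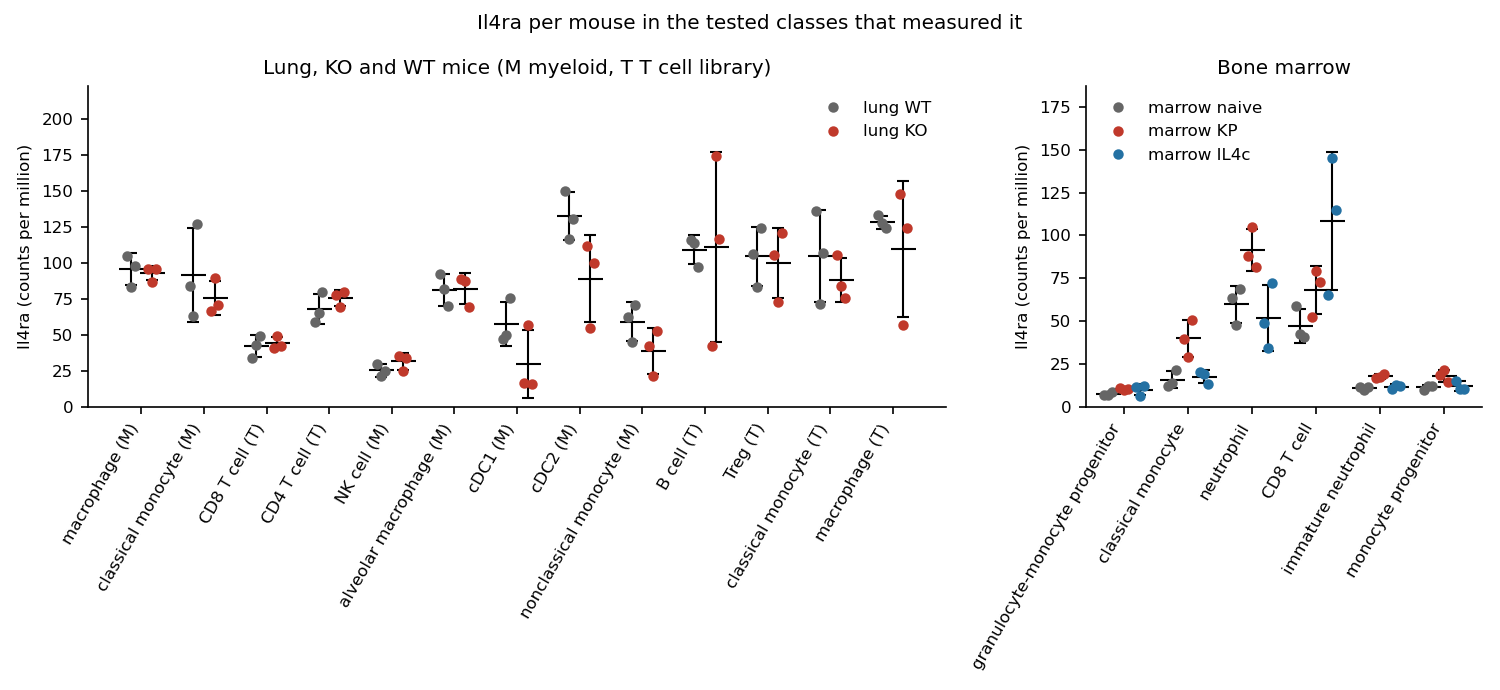
Il4ra expression (CPM, y axis) in each class (x axis), with 1 dot per mouse and bars for the mean and SD of 3 mice, in KO and WT lung (M, myeloid library, and T, T cell library) and in naive, KP and IL4c bone marrow. KO and WT dots lie at like levels in most lung classes, whereas KP monocyte-like cells (39.7 CPM) lie above naive ones (15.7 CPM).

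In lung macrophage-like cells, Cxcl2, a neutrophil-attracting chemokine, was higher in KO mice (973 ± 84.8 CPM against 550.2 ± 64.4 CPM, log2 0.82 ± 0.12, adjusted p = 0.0384), in 3 of 3 mice. Wfdc21, a small protease inhibitor-like protein, was lower (198 ± 24.7 CPM against 364 ± 22.4 CPM, log2 -0.88 ± 0.13, adjusted p = 0.0384), also in 3 of 3. These were the only 2 of 7305 genes called. Cxcl2 belongs to the NF-kB inflammatory list, where of 15 members 1 rose and 0 fell (4 adjusted over the list alone, median 0.45, adjusted p = 7.06e-08, adjusted p = 0.0721 with an estimated correlation). In the type I interferon response list, of 11 members 0 rose and 0 fell (3 adjusted over the list alone, median -0.40, adjusted p = 7.06e-08, adjusted p = 0.616 with an estimated correlation). Ifi27l2a was at -1.03 ± 0.20, adjusted p = 0.330. For genes of the IL-4 and STAT6 response, of 14 members 0 rose and 0 fell (1 adjusted over the list alone, median -0.06, mean 0.01, test upward, adjusted p = 0.766), with Egr2 at 0.78 ± 0.22, adjusted p = 0.888 and Ch25h at 0.75 ± 0.34, adjusted p = 0.903. For the lipid-associated TREM2 macrophage list, of 18 members 0 rose and 0 fell (1 adjusted over the list alone, median -0.01, adjusted p = 0.346), with lipoprotein lipase Lpl at -0.59 ± 0.15, adjusted p = 0.888. Markers of other cells and stress moved without passing, in groups without overlap, with Epcam at -1.73 ± 0.50, Krt19 at -1.08 ± 0.31, Ly6c2 at -1.50 ± 0.49 and Egr1 at 0.62 ± 0.16 (adjusted p = 0.888 each). In all, 374 genes had an unadjusted p under 0.05, and groups did not overlap for 818 genes (11.2%, against 10% by chance). Both calls were lost without KO mouse 1, KO mouse 2, WT mouse 1 or WT mouse 2 (0 genes each), with a replicate term, with the stricter cell filter and at either other resolution (0 genes each). Without KO mouse 3 or with doublets kept the count was 1, and without WT mouse 3 it was 6.

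Lung monocyte-like cells of KO mice had more AY036118, a transcript that overlaps a ribosomal RNA repeat (5329 ± 1270 CPM against 2169 ± 412 CPM, log2 1.29 ± 0.14, adjusted p = 0.000381). Eno3, a glycolytic enolase outside the naming rule and named after its values were seen, was lower (4.43 ± 2.02 CPM against 33.2 ± 14.4 CPM, log2 -2.82 ± 0.46, adjusted p = 0.0354). These were the 2 genes called of 6244, each higher or lower in 3 of 3 mice. The monocyte marker Ly6c2 did not pass, at -0.61 ± 0.19, adjusted p = 0.427. For the monocyte lineage list, of 15 members 0 rose and 0 fell (2 adjusted over the list alone, median 0.05, mean -0.02, test downward, adjusted p = 0.807). In the type I interferon response list, of 16 members 0 rose and 0 fell (1 adjusted over the list alone, median -0.30, adjusted p = 4.09e-07, adjusted p = 0.604 with an estimated correlation). Ifi27l2a was at -0.53 ± 0.15, adjusted p = 0.337 and Zbp1 at -0.51 ± 0.17, adjusted p = 0.455. For dissociation stress genes, of 13 members 0 rose and 0 fell (0 adjusted over the list alone, median 0.27, adjusted p = 0.00108, adjusted p = 0.604 with an estimated correlation). Hspa1a was at 1.52 ± 0.48, adjusted p = 0.448, and for the respiratory chain, of 27 members 0 rose and 0 fell (0 adjusted over the list alone, median -0.18, adjusted p = 4.09e-07, adjusted p = 0.604 with an estimated correlation). The IL-4 and STAT6 response list had under 5 measured members and was not tested here, with its member Chil3 at 0.48 ± 0.20, adjusted p = 0.592. Unadjusted p was under 0.05 for 493 genes, and 798 (12.8%, chance 10%) did not overlap. AY036118 was called under every alternative. It rose alike in CD8 (1.32) and CD4 T-like cells (1.13), so a lane effect stays open. Eno3 was lost without KO mouse 1 (adjusted p = 0.104) or 3 (0.0948), with DESeq2 (0.0563) and under the stricter filter (0.0645). It had no value without WT mouse 2 or 3 and at resolution 2.0. The count was 1 without KO mouse 1 or 3 or WT mouse 2 or 3, 1 at resolution 2.0 and 6 without KO mouse 2.

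In CD8 T-like cells of the lung T cell library, 14 of 8560 genes were called in KO mice, 9 higher and 5 lower, in 3 of 3 mice each. Tnfrsf4 (OX40), an activation-induced costimulatory receptor, was lower (37.0 ± 8.09 CPM against 108 ± 31.0 CPM, log2 -1.50 ± 0.22, adjusted p = 0.0183). Interferon-induced Ifitm2 (-1.30 ± 0.22, adjusted p = 0.0442) was lower, and the T cell receptor segment Trbv19 (0.89 ± 0.12, adjusted p = 0.00878), the phosphatase gene Dusp7 (1.2 ± 0.21, adjusted p = 0.0487) and AY036118 (1.32 ± 0.14, adjusted p = 0.00103) were higher. The other 9 were immunoglobulin genes, such as Ighg1 (18.1 ± 7.37 CPM against 0.410 ± 0.172 CPM) and Igkv3-4 (0.199 ± 0.345 CPM against 23.4 ± 1.19 CPM), which B-lineage and not T cells make. Of the called genes, all but Tnfrsf4 and AY036118 fell outside the naming rule and were named after their values were seen. In the T cell exhaustion list, of 14 members 0 rose and 0 fell (5 adjusted over the list alone, median -0.72, adjusted p = 4.08e-10, adjusted p = 0.227 with an estimated correlation). Tnfrsf9 was at -1.17 ± 0.27, adjusted p = 0.189 and Lag3 at -0.91 ± 0.27, adjusted p = 0.25. In the T cell naive and memory list, of 11 members 0 rose and 0 fell (5 adjusted over the list alone, median 0.34, adjusted p = 2.38e-07, adjusted p = 0.227 with an estimated correlation). Il7r was at 0.44 ± 0.11, adjusted p = 0.194 and Klf2 at 0.39 ± 0.10, adjusted p = 0.209. For T cell effector genes, of 15 members 0 rose and 0 fell (2 adjusted over the list alone, median -0.21, adjusted p = 0.0292, adjusted p = 0.696 with an estimated correlation). Ccl4 was at -1.01 ± 0.28, adjusted p = 0.228. For the respiratory chain, of 27 members 0 rose and 0 fell (12 adjusted over the list alone, median -0.22, adjusted p = 9.49e-12, adjusted p = 0.174 with an estimated correlation). For type 1 helper genes, of 10 members 0 rose and 0 fell (1 adjusted over the list alone, median 0.05, mean -0.01, test downward, adjusted p = 0.957), and for T cell markers, of 6 members 0 rose and 0 fell (0 adjusted over the list alone, median -0.03, adjusted p = 0.257). The adjusted p of Tnfrsf4 was 0.0635, 0.0689 and 0.0855 without KO mice 1, 2 and 3, 0.0595 and 0.0866 without WT mice 1 and 3, 0.0696 under the stricter filter and 0.0570 at resolution 0.5. Trbv19 was lost without KO mouse 1 (0.110), WT mouse 1 (0.0595) or WT mouse 3 (0.0636), Ifitm2 in 7 and Dusp7 in 10 of 14 alternatives. Counts were 9 without KO mouse 1 and 63 without WT mouse 2. Groups did not overlap for 1515 genes (17.7%, chance 10%).

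CD4 T-like cells of KO lungs had 47 of 8707 genes called, 19 higher and 28 lower. The IL-7 receptor Il7r was higher (529 ± 36.2 CPM against 400.2 ± 20.3 CPM, log2 0.40 ± 0.07, adjusted p = 0.00776), as was Lef1, a transcription factor of naive T cells (0.34 ± 0.07, adjusted p = 0.0350). In the T cell naive and memory list, of 11 members 2 rose and 0 fell (4 adjusted over the list alone, median 0.16, adjusted p = 0.00017, adjusted p = 0.244 with an estimated correlation). The chemokine Ccl5 (0.64 ± 0.12, adjusted p = 0.0170) rose, while Tnfrsf18 (GITR, -0.51 ± 0.11, adjusted p = 0.0350) and interferon-induced Ifi27l2a (-0.62 ± 0.12, adjusted p = 0.0137) and Ifitm2 (-0.91 ± 0.20, adjusted p = 0.0350) fell. In the type I interferon response list, of 13 members 0 rose and 1 fell (3 adjusted over the list alone, median -0.33, adjusted p = 0.000146, adjusted p = 0.193 with an estimated correlation). Respiratory chain genes were lower, the list call that held with an estimated correlation. There, of 27 members 0 rose and 1 fell (19 adjusted over the list alone, median -0.20, adjusted p = 6.36e-12, adjusted p = 0.0319 with an estimated correlation). Ndufa4 was at -0.38 ± 0.07, adjusted p = 0.0178. The proteasome genes Psmb3 (-0.41 ± 0.07, adjusted p = 0.00744) and Pomp (-0.41 ± 0.08, adjusted p = 0.0178) fell. For IL-4 and STAT6 response genes, of 6 members 0 rose and 0 fell (3 adjusted over the list alone, median -0.31, adjusted p = 0.00890, adjusted p = 0.193 with an estimated correlation). For mitochondrially encoded genes, of 13 members 2 rose and 0 fell (8 adjusted over the list alone, median 0.24, adjusted p = 6.36e-12, adjusted p = 0.193 with an estimated correlation). Markers of other cells moved too. Lyz2, made by myeloid cells, fell (-0.53 ± 0.08, adjusted p = 0.00200), and in the macrophage contamination list of 5 members 0 rose and 1 fell (3 adjusted over the list alone, median -0.53, adjusted p = 0.000146, adjusted p = 0.151 with an estimated correlation). Jchain (1.23 ± 0.23, adjusted p = 0.0137) and Igha (0.92 ± 0.15, adjusted p = 0.00576), made by plasma cells, rose. AY036118 rose (1.13 ± 0.08, adjusted p = 1.47e-07) and was the only one of 16 named called genes called under every alternative. Without WT mouse 3, 13 of the 16 were not called, and without KO mouse 2, 11 were not. Without WT mouse 3 the adjusted p was 0.106 for Il7r, 0.189 for Ccl5 and 0.188 for Lef1, and Lyz2 was lost only under the stricter filter (0.608). Counts were 22 without KO mouse 2, 31 without WT mouse 1 and 16 without WT mouse 3. Groups did not overlap for 1484 genes (17.0%, chance 10%).

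No class share of lung cells reached p = 0.05, since 3 mice against 3 cannot give an exact permutation p below 0.10. Type 2 innate lymphoid (ILC2)-like cells, a source of type 2 cytokines, made up 3.33% ± 0.827 against 2.1% ± 0.705 of KO and WT myeloid libraries. Regulatory T-like cells made up 2.91% ± 0.466 against 5.93% ± 1.71 of T cell libraries, and endothelial-like cells 1.06% ± 0.558 against 0.322% ± 0.179. In these 3 classes the mice of KO and WT did not overlap, against 10% by chance (exact two-sided permutation p = 0.10, smallest adjusted p 0.891 over 14 myeloid and 0.557 over 13 T cell library classes). Macrophage-like cells made up 6.97% ± 2.96 against 9.89% ± 1.62, monocyte-like cells 8.73% ± 1.39 against 10.1% ± 0.845 and alveolar macrophage-like cells 24.8% ± 10.9 against 30.9% ± 1.85 of myeloid libraries. Under the stricter cell filter no myeloid class was free of overlap.

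The KP comparison asks how a lung tumor changes myeloid precursors in bone marrow. In KP monocyte-like cells 2196 of 10209 genes were called, 1100 higher and 1096 lower than in naive mice. Il1r2, the decoy receptor of IL-1, went from 1.01 ± 0.494 CPM to 207 ± 209 CPM (log2 7.65 ± 1.18, adjusted p = 0.00223), and the calprotectin subunit S100a8 was at 8329 ± 5460 CPM against 1199 ± 175 CPM (log2 2.80 ± 0.55, adjusted p = 0.00659). The matrix proteoglycan Vcan rose (808 ± 324 CPM against 78.4 ± 11.5 CPM, log2 3.36 ± 0.32, adjusted p = 0.000209). Interferon-induced genes fell, such as Samd9l (16.6 ± 9.94 CPM against 92.8 ± 7.28 CPM, log2 -2.45 ± 0.32, adjusted p = 0.000923). KP mouse 2 changed least, with Il1r2 at 21.6 CPM against 167 and 433, S100a8 at 2430 against 9353 and 13210 and Samd9l at 27.6 against 14.0 and 8.29. Il1r2 was at 6.52 (log2) without KP mouse 3. Of the 71 named genes called, 69 had groups that did not overlap, Chil3 and Mgl2 being the exceptions.

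Type I interferon response genes fell in these KP monocyte-like cells, where of 17 members 0 rose and 15 fell (16 adjusted over the list alone, median -2.43, adjusted p = 8.78e-10, adjusted p = 0.374 with an estimated correlation). The tetherin gene Bst2 was at -1.78 ± 0.32, adjusted p = 0.00462. In the interferon-gamma response list, of 16 members 0 rose and 7 fell (8 adjusted over the list alone, median -1.35, adjusted p = 1.07e-06, adjusted p = 0.466 with an estimated correlation). For MHC class II presentation, of 12 members 1 rose and 3 fell (8 adjusted over the list alone, median -1.54, adjusted p = 0.00699, adjusted p = 0.466 with an estimated correlation). The peptide loader H2-DMa was at -1.19 ± 0.22, adjusted p = 0.00530. The suppressive neutrophil list went the other way, and of 12 members 7 rose and 1 fell (9 adjusted over the list alone, median 1.36, adjusted p = 2.47e-05, adjusted p = 0.275 with an estimated correlation). The pattern receptor Clec4e was at 2.45 ± 0.31, adjusted p = 0.000834 and Ifitm1 at 2.31 ± 0.35, adjusted p = 0.00194. For primary granule genes, of 10 members 6 rose and 1 fell (7 adjusted over the list alone, median 0.45, adjusted p = 0.00987, adjusted p = 0.275 with an estimated correlation). Ms4a3, the gene of the Cre driver, was at 1.59 ± 0.28, adjusted p = 0.00460. In the neutrophil lineage list, of 14 members 6 rose and 0 fell (7 adjusted over the list alone, median 0.89, adjusted p = 0.00222, adjusted p = 0.499 with an estimated correlation). The collagenase Mmp8 was at 2.90 ± 0.39, adjusted p = 0.00115. Markers of contaminating neutrophils rose in the same cells, and there of 7 members 4 rose and 0 fell (4 adjusted over the list alone, median 1.68, adjusted p = 0.00699, adjusted p = 0.466 with an estimated correlation). The siderophore-binding Lcn2 was at 3.32 ± 0.63, adjusted p = 0.00579. Other large rises were Lrg1 (4.59 ± 0.59, adjusted p = 0.000843), Crispld2 (5.58 ± 0.81, adjusted p = 0.00160), Zfp36l1, an mRNA decay factor (4.41 ± 0.55, adjusted p = 0.000762) and the acute-phase gene Saa3 (3.47 ± 0.71, adjusted p = 0.00829). Cd38, an ectoenzyme that consumes NAD, had 1444 UMIs in KP and 1 in naive cells (ratio of CPM 795, exact 95% counting interval 142 to 31430).

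Receptor and regulator genes changed in KP monocyte-like cells as well. Among cytokine receptors, of 13 members 4 rose and 3 fell (10 adjusted over the list alone, median -0.23, mean 0.10, test upward, adjusted p = 0.715), and besides Il4ra the rises included Il13ra1, the partner of Il4ra in the type II receptor (0.98 ± 0.17, adjusted p = 0.00415), and Csf2rb, the shared chain of the GM-CSF receptor (0.75 ± 0.10, adjusted p = 0.00108). Among myelopoiesis transcription factors, of 12 members 2 rose and 3 fell (5 adjusted over the list alone, median -0.11, adjusted p = 0.445), with Cebpa at 0.74 ± 0.14, adjusted p = 0.00573, Stat3 at 0.76 ± 0.14, adjusted p = 0.00513 and Irf8, which directs monocyte fate, at -0.72 ± 0.08, adjusted p = 0.000525. In the monocyte lineage list, of 15 members 4 rose and 8 fell (13 adjusted over the list alone, median -0.40, mean 0.01, test downward, adjusted p = 0.0997), with the fractalkine receptor Cx3cr1, a marker of nonclassical monocytes, at -2.55 ± 0.51, adjusted p = 0.00695 and lysozyme Lyz2 at -0.73 ± 0.07, adjusted p = 0.000286. In the IL-4 and STAT6 response list, of 5 members 1 rose and 3 fell (5 adjusted over the list alone, median -1.22, adjusted p = 0.0701). In the NF-kB inflammatory list, of 10 members 2 rose and 0 fell (2 adjusted over the list alone, median 0.03, adjusted p = 0.116), Ier3 being at 2.67 ± 0.34, adjusted p = 0.000838. For dissociation stress, of 13 members 4 rose and 2 fell (8 adjusted over the list alone, median -0.07, mean 0.37, test upward, adjusted p = 0.698), with Egr1 at 3.29 ± 0.54, adjusted p = 0.00317 and Fos at 1.55 ± 0.29, adjusted p = 0.00533. For hypoxia and glycolysis, of 15 members 8 rose and 0 fell (8 adjusted over the list alone, median 0.36, adjusted p = 0.00294, adjusted p = 0.374 with an estimated correlation). In the immunosuppression list, of 6 members 0 rose and 2 fell (3 adjusted over the list alone, median -0.34, adjusted p = 0.0799). Plasma cell transcripts Igkc (-1.48 ± 0.13, adjusted p = 0.000129) and Jchain (-1.12 ± 0.21, adjusted p = 0.00542) fell. KP cells of this class lay mainly in cluster 4 (1105 KP, 1 IL4c and 14 naive cells) and naive ones in cluster 2 (15 KP, 457 IL4c and 1185 naive). Genes without overlap numbered 4086 (40.0%, chance 10%). Counts were 1162 without KP mouse 1, 4004 without KP mouse 2, 1072, 909 and 1028 without naive mice 1, 2 and 3, and 1267 with the 6 compared libraries alone. Of 71 named genes called, 49 were called under every alternative, and 18 were lost without KP mouse 1, 11 without KP mouse 3, 16 without naive mouse 2 and 14 without naive mouse 3.

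**Figure D2:**
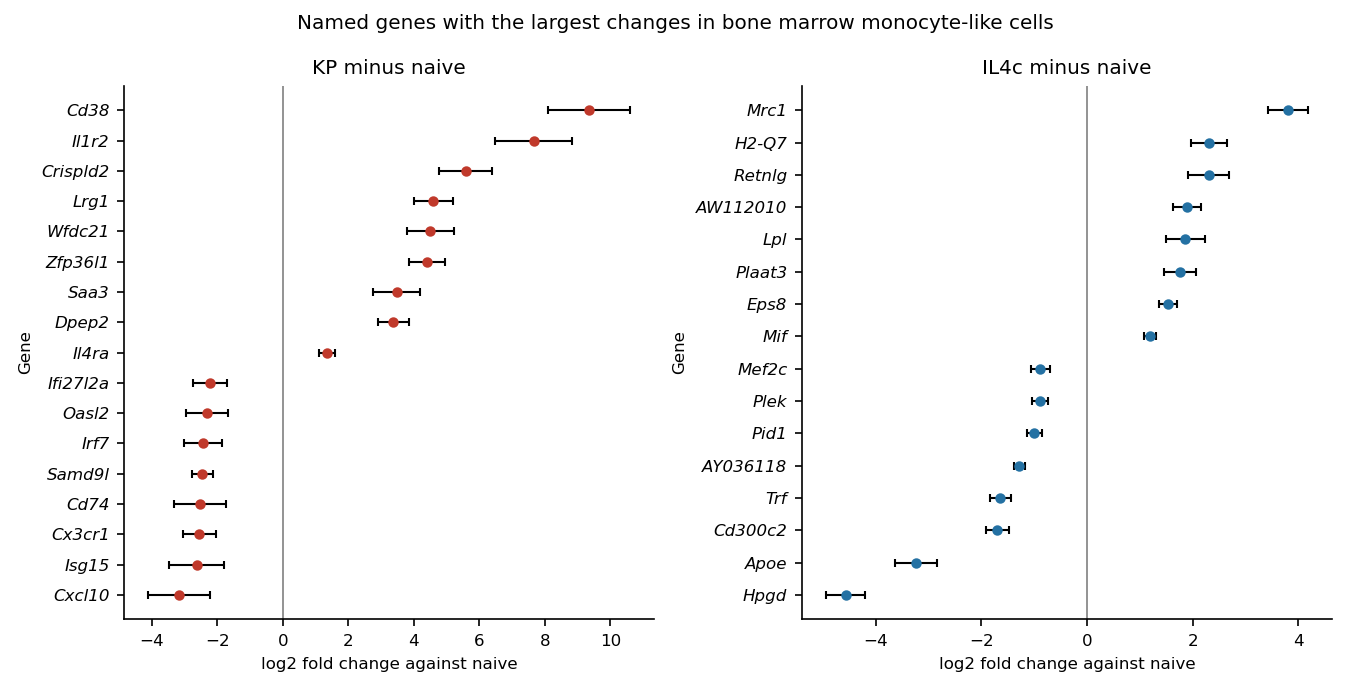
Log2 fold change against naive mice (x axis) with its SE for genes with the largest changes and Il4ra in bone marrow monocyte-like cells (y axis), for KP and IL4c mice, 3 mice per group. Il1r2, Crispld2 and Lrg1 lie to the right in KP mice, and Mrc1 and H2-Q7 in IL4c mice.

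KP neutrophil-like cells had 566 of 3907 genes called, 261 higher and 305 lower. Genes of the stefin A family, which encode cysteine protease inhibitors, rose, with Stfa2 at 849.6 ± 529.9 CPM against 15.9 ± 27.6 CPM (log2 5.68 ± 0.74, adjusted p = 0.000185). All 17 naive UMIs of Stfa2 came from naive mouse 2, without which the naive level was 0 and the fitted log2 value 12.74, so its size rests on that mouse. Its relatives Cstdc5 (4.50 ± 0.52, adjusted p = 5.92e-05), Stfa3 (3.52 ± 0.51, adjusted p = 0.00037), Stfa1 (3.29 ± 0.53, adjusted p = 0.00085), Cstdc4 (2.55 ± 0.22, adjusted p = 4.90e-06) and Stfa2l1 (2.32 ± 0.23, adjusted p = 1.35e-05) rose too, though these are near-identical copies among which reads are hard to assign. Wfdc17 (1265 ± 719 CPM against 175 ± 93.5 CPM, log2 2.83 ± 0.40, adjusted p = 0.000298) and Ifitm1 (1.68 ± 0.34, adjusted p = 0.00397) rose in the suppressive neutrophil list, where of 12 members 3 rose and 4 fell (8 adjusted over the list alone, median -0.42, adjusted p = 0.302). Interferon-induced Slfn5 (-3.72 ± 0.53, adjusted p = 0.000325), Slfn8 (-2.59 ± 0.45, adjusted p = 0.00149), Xaf1 (-2.19 ± 0.46, adjusted p = 0.00512) and Irf7 (-2.12 ± 0.36, adjusted p = 0.00126) fell. KP mouse 2 stood apart, with Slfn5 at 32.4 CPM against 5.90 and 1.69, and without it Slfn5 was at -5.06 and Slfn8 at -3.43. Of 47 named genes called, 45 had groups without overlap, Cebpd and Csf1r being the exceptions.

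In the type I interferon response list of KP neutrophil-like cells, of 14 members 0 rose and 8 fell (12 adjusted over the list alone, median -2.18, adjusted p = 1.47e-09, adjusted p = 0.439 with an estimated correlation). For immunosuppression, of 8 members 1 rose and 3 fell (6 adjusted over the list alone, median -0.88, adjusted p = 0.00408, adjusted p = 0.439 with an estimated correlation). Cyclooxygenase-2 Ptgs2 was at -3.40 ± 0.59, adjusted p = 0.00142. NF-kB inflammatory genes split, Nlrp3 at -1.84 ± 0.26, adjusted p = 0.000325 and Nfkbia at 1.03 ± 0.16, adjusted p = 0.0006, and of 7 members 2 rose and 3 fell (6 adjusted over the list alone, median -0.44, adjusted p = 0.229). In the neutrophil lineage list, of 13 members 6 rose and 1 fell (8 adjusted over the list alone, median 0.29, adjusted p = 0.000239, adjusted p = 0.439 with an estimated correlation). For neutrophil contamination, of 7 members 5 rose and 0 fell (5 adjusted over the list alone, median 0.81, adjusted p = 1.97e-07, adjusted p = 0.215 with an estimated correlation). The immature-stage granule gene Ngp rose (1.35 ± 0.14, adjusted p = 2.42e-05), but not at resolution 0.5 (adjusted p = 0.239) or 2.0 (0.124). The G-CSF receptor Csf3r fell (-0.84 ± 0.19, adjusted p = 0.00838), and Cebpb, a factor of emergency granulopoiesis, rose (0.76 ± 0.15, adjusted p = 0.00331). For hypoxia and glycolysis, of 11 members 5 rose and 1 fell (8 adjusted over the list alone, median 0.70, adjusted p = 0.0112, adjusted p = 0.439 with an estimated correlation). For the respiratory chain, of 27 members 10 rose and 0 fell (11 adjusted over the list alone, median 0.43, adjusted p = 2.59e-06, adjusted p = 0.215 with an estimated correlation). The monocyte gene Zeb2 fell (-1.80 ± 0.23, adjusted p = 0.000157) while Id2 rose (2.24 ± 0.41, adjusted p = 0.00195). B-lineage Ighm (-2.89 ± 0.31, adjusted p = 3.09e-05) and Igkc (-1.79 ± 0.21, adjusted p = 5.92e-05) fell. KP cells lay mainly in cluster 6 (1015 KP, 13 IL4c, 30 naive) and naive ones in cluster 9 (49 KP, 459 IL4c, 415 naive). Genes without overlap numbered 1242 (31.8%, chance 10%). Counts were 318 without KP mouse 1, and 306, 301 and 328 without naive mice 1, 2 and 3. Of 47 named genes called, 36 were called under every alternative.

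**Figure D3:**
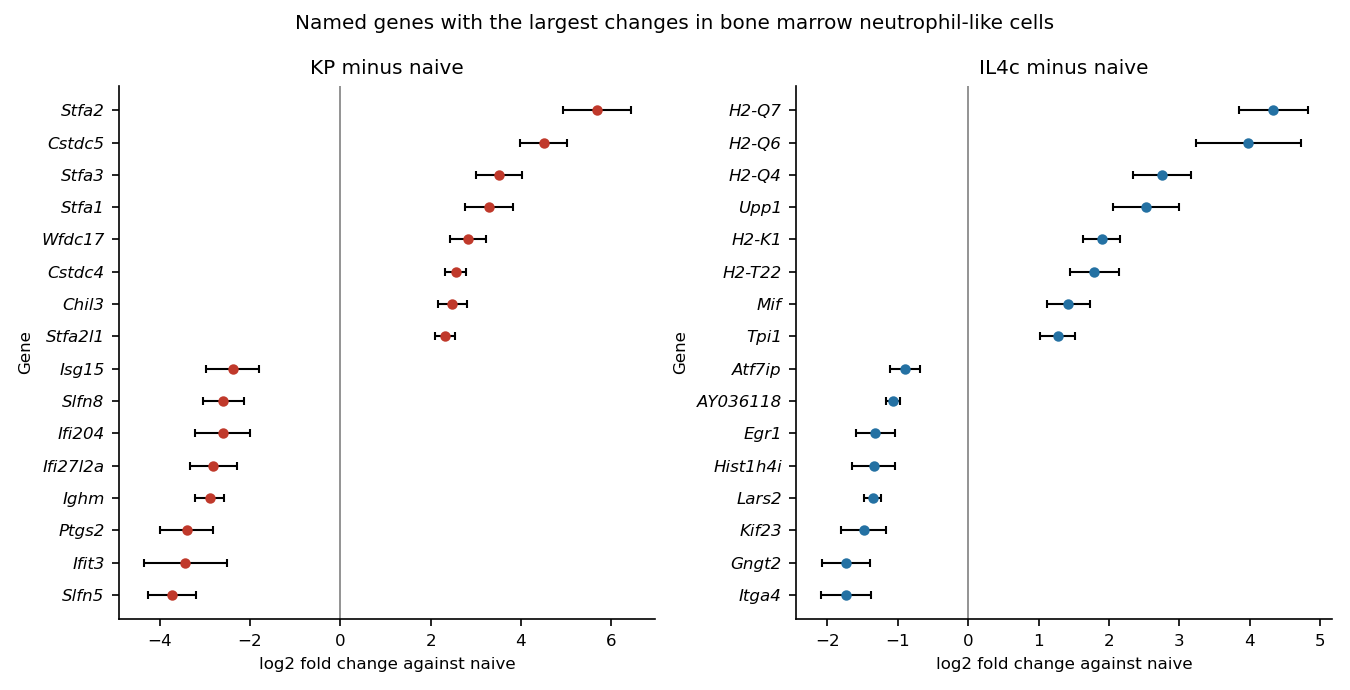
Log2 fold change against naive mice (x axis) with its SE for genes with the largest changes in bone marrow neutrophil-like cells (y axis), for KP and IL4c mice, 3 mice per group. Stefin A family genes lie farthest right in KP mice, and H2-Q7 in IL4c mice.

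Granulocyte-monocyte progenitor-like cells of KP mice had 748 of 8371 genes called, 406 higher and 342 lower. Stfa1 (70.7 ± 33.4 CPM against 2.20 ± 3.36 CPM, log2 4.78 ± 0.56, adjusted p = 5.51e-06) and interferon-induced family member Ifitm6 (282 ± 103 CPM against 39.8 ± 13.2 CPM, log2 2.90 ± 0.24, adjusted p = 3.39e-08) rose, as did the calcium binder S100a6 (2.43 ± 0.31, adjusted p = 1.45e-05). Stfa1 had 12 naive UMIs, at 6.06, 0.534 and 0 CPM, and was at 7.45 without naive mouse 1. Il1r2 (1.97 ± 0.22, adjusted p = 3.12e-06), cold-inducible Cirbp (1.95 ± 0.23, adjusted p = 5.51e-06) and the histone gene Hist1h2ap (1.99 ± 0.20, adjusted p = 5.60e-07) rose. Siglecg (-1.88 ± 0.28, adjusted p = 0.000113), Lyz2 (-1.22 ± 0.19, adjusted p = 0.000155) and the lipolysis inhibitor G0s2 (-1.12 ± 0.19, adjusted p = 0.000358) fell. Of 47 named genes called, 44 had groups without overlap, Ifi27l2a, Cenpf and F13a1 being the exceptions.

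In these KP progenitor-like cells, respiratory chain genes rose, as of 27 members 14 rose and 0 fell (15 adjusted over the list alone, median 0.34, adjusted p = 6.95e-14, adjusted p = 0.0896 with an estimated correlation). Uqcr11 was at 0.80 ± 0.10, adjusted p = 1.36e-05. In the suppressive neutrophil list, of 10 members 4 rose and 0 fell (4 adjusted over the list alone, median 0.37, adjusted p = 0.00619, adjusted p = 0.336 with an estimated correlation). In the type I interferon response list, of 13 members 0 rose and 3 fell (6 adjusted over the list alone, median -1.22, adjusted p = 0.000306, adjusted p = 0.410 with an estimated correlation), and the immunoproteasome gene Psmb9 fell (-0.62 ± 0.12, adjusted p = 0.00256). Monocyte lineage genes F13a1 (1.74 ± 0.35, adjusted p = 0.00274) and Fn1 (2.89 ± 0.36, adjusted p = 1.22e-05) rose, although DESeq2 gave no adjusted p for Fn1, and for that list of 10 members 3 rose and 2 fell (6 adjusted over the list alone, median 0.49, adjusted p = 0.507). Ribosomal protein genes rose, and of 88 members 40 rose and 1 fell (49 adjusted over the list alone, median 0.21, adjusted p = 5.18e-30, adjusted p = 0.249 with an estimated correlation). Ighm (-1.75 ± 0.30, adjusted p = 0.000424) and Igkc (-1.04 ± 0.19, adjusted p = 0.000954) fell here too, in bone marrow whose B-like share was lower. Genes without overlap numbered 2107 (25.2%, chance 10%). Counts were 364, 329 and 462 without naive mice 1, 2 and 3, 450 with DESeq2 and 496 with the 6 compared libraries. Of 47 named genes called, 26 were called under every alternative, and 11 each were lost without naive mouse 1 or 2.

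The IL4c comparison asks what IL-4c treatment changes in the same classes. In IL4c monocyte-like cells 194 of 10209 genes were called, 102 higher and 92 lower. The mannose receptor Mrc1 (61.1 ± 7.80 CPM against 4.4 ± 1.61 CPM, log2 3.80 ± 0.38, adjusted p = 0.00101) and the lectin Mgl2 (36.9 ± 5.12 CPM against 3.13 ± 2.01 CPM, log2 3.53 ± 0.37, adjusted p = 0.00145), both known IL-4 targets, rose. The prostaglandin-degrading enzyme Hpgd (2.80 ± 2.87 CPM against 76.0 ± 12.2 CPM, log2 -4.57 ± 0.37, adjusted p = 0.000272) and apolipoprotein Apoe (87.2 ± 3.89 CPM against 821 ± 413 CPM, log2 -3.23 ± 0.40, adjusted p = 0.00314) fell. All 35 named genes called had groups without overlap. In the IL-4 and STAT6 response list, of 5 members 2 rose and 0 fell (2 adjusted over the list alone, median 1.22, adjusted p = 7.40e-11, adjusted p = 0.0153 with an estimated correlation). For hypoxia and glycolysis, of 15 members 7 rose and 0 fell (9 adjusted over the list alone, median 0.59, adjusted p = 6.35e-13, adjusted p = 0.0276 with an estimated correlation). Gapdh was at 0.74 ± 0.09, adjusted p = 0.00314. Among lipid-associated TREM2 macrophage genes, of 14 members 3 rose and 1 fell (8 adjusted over the list alone, median 0.39, adjusted p = 0.000178, adjusted p = 0.0376 with an estimated correlation). For primary granule genes, of 10 members 3 rose and 0 fell (7 adjusted over the list alone, median 0.44, adjusted p = 1.02e-06, adjusted p = 0.0199 with an estimated correlation). Neutrophil markers moved too, and for neutrophil contamination, of 7 members 1 rose and 0 fell (7 adjusted over the list alone, median 1.83, adjusted p = 3.49e-08, adjusted p = 0.142 with an estimated correlation). There Retnlg was at 2.30 ± 0.39, adjusted p = 0.0146, and Ngp did not pass, with IL4c mouse 1 at 2236 CPM against 386 and 562. In the monocyte lineage list, of 15 members 0 rose and 2 fell (5 adjusted over the list alone, median -0.28, adjusted p = 0.000115, adjusted p = 0.0276 with an estimated correlation). In the T cell effector list, whose members include Gzma, of 8 members 3 rose and 0 fell (5 adjusted over the list alone, median 1.38, adjusted p = 5.33e-08, adjusted p = 0.0376 with an estimated correlation). T cell markers Cd3d (2.39 ± 0.61, adjusted p = 0.0802) and Trbc2 (2.30 ± 0.67, adjusted p = 0.118) did not pass but lay higher in 3 of 3 IL4c mice. AW112010 rose (1.89 ± 0.26, adjusted p = 0.00589, source untested).

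Other rises in IL4c monocyte-like cells included the cytokine Mif (1.19 ± 0.11, adjusted p = 0.000767), the actin regulator Eps8 (1.53 ± 0.17, adjusted p = 0.00220) and nonclassical MHC gene H2-Q7 (2.31 ± 0.34, adjusted p = 0.00836). H2-Q7 was lost without IL4c mouse 2 (adjusted p = 0.0502) or 3 (0.0521) or naive mouse 1 (0.0726) or 3 (0.0730). Cd300c2 (-1.70 ± 0.22, adjusted p = 0.00393), transferrin Trf (-1.64 ± 0.21, adjusted p = 0.00359), AY036118 (-1.28 ± 0.10, adjusted p = 0.000272) and Cebpb (-0.56 ± 0.07, adjusted p = 0.00314) fell, and among myelopoiesis transcription factors of 12 members 0 rose and 3 fell (3 adjusted over the list alone, median -0.12, adjusted p = 0.00771, adjusted p = 0.174 with an estimated correlation). Among cytokine receptors, of 13 members 0 rose and 2 fell (4 adjusted over the list alone, median -0.18, adjusted p = 0.00771, adjusted p = 0.146 with an estimated correlation). The class lay in clusters 2, 8 and 19 in IL4c (457, 339 and 275 cells) and naive mice (1185, 355 and 189 cells). Genes without overlap numbered 3196 (31.3%, chance 10%). Counts were 82, 56 and 41 without IL4c mice 1, 2 and 3, 126, 673 and 567 without KP mice 1, 2 and 3, which share the dispersion estimate, and 39, 72 and 35 without naive mice 1, 2 and 3. Settings listed below gave 371 to 1286. Of 35 named genes called, 15 were called under every alternative, and 16 to 20 were lost without IL4c mouse 2 or 3 or naive mouse 1 or 3.

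IL4c neutrophil-like cells had 50 of 3907 genes called, 39 higher and 11 lower. The largest rises included genes of the MHC class I family, a group not tested as a list, with H2-Q7 at 377 ± 179 CPM against 17.6 ± 11.1 CPM (log2 4.33 ± 0.49, adjusted p = 0.000144), H2-K1 at 1920 ± 430.1 CPM against 515 ± 38.9 CPM (log2 1.90 ± 0.27, adjusted p = 0.000964) and H2-Q4 at 2.75 ± 0.41, adjusted p = 0.00160. Granule genes Ngp (1.10 ± 0.14, adjusted p = 0.000618) and Lcn2 (0.86 ± 0.11, adjusted p = 0.000618) and galectin-3 gene Lgals3 (0.71 ± 0.11, adjusted p = 0.00174) rose, whereas mitochondrial leucyl-tRNA synthetase Lars2 (-1.36 ± 0.12, adjusted p = 1.58e-05) and AY036118 (-1.06 ± 0.10, adjusted p = 1.92e-05) fell. The 24 named genes called had groups without overlap. In the interferon-gamma response list, of 8 members 2 rose and 0 fell (4 adjusted over the list alone, median 1.07, adjusted p = 4.96e-07, adjusted p = 0.263 with an estimated correlation), with the immunoproteasome genes Psmb8 (0.80 ± 0.14, adjusted p = 0.00760) and Psmb9 (1.04 ± 0.18, adjusted p = 0.00464). Both were lost without naive mouse 2 (adjusted p = 0.0507 and 0.0507). For hypoxia and glycolysis, of 11 members 3 rose and 0 fell (7 adjusted over the list alone, median 0.63, adjusted p = 7.11e-09, adjusted p = 0.158 with an estimated correlation). In the neutrophil lineage list, of 13 members 3 rose and 0 fell (10 adjusted over the list alone, median 0.43, adjusted p = 4.31e-09, adjusted p = 0.203 with an estimated correlation). For neutrophil contamination, of 7 members 3 rose and 0 fell (7 adjusted over the list alone, median 0.65, adjusted p = 3.78e-13, adjusted p = 0.0854 with an estimated correlation). H2-Q4 had no adjusted p from DESeq2. Genes without overlap numbered 863 (22.1%, chance 10%). Counts were 27 and 19 without IL4c mice 2 and 3, 121 and 167 without KP mice 2 and 3, and 23, 19 and 26 without naive mice 1, 2 and 3. Settings listed below gave 91 to 259, and 8 of the 24 named genes were called under every alternative.

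IL4c progenitor-like cells had 84 of 8371 genes called, 59 higher and 25 lower. H2-Q7 (286 ± 76.0 CPM against 28.0 ± 3.50 CPM, log2 3.32 ± 0.19, adjusted p = 2.06e-10) and H2-Q6 (60.4 ± 16.9 CPM against 3.23 ± 1.08 CPM, log2 4.10 ± 0.31, adjusted p = 3.06e-08) rose, as did endothelial lipase Lipg (3.46 ± 0.39, adjusted p = 7.28e-06), the peptide transporter Tap1 (1.62 ± 0.17, adjusted p = 1.78e-06) and the antiviral Ifitm3 (1.56 ± 0.13, adjusted p = 9.83e-08). In the interferon-gamma response list, of 9 members 5 rose and 0 fell (9 adjusted over the list alone, median 0.84, adjusted p = 3.30e-20, adjusted p = 0.0382 with an estimated correlation). Psmb8 was at 0.59 ± 0.10, adjusted p = 0.00139. In the type I interferon response list, of 13 members 4 rose and 0 fell (11 adjusted over the list alone, median 1.38, adjusted p = 6.97e-18, adjusted p = 0.0488 with an estimated correlation). Oasl2 was at 2.39 ± 0.39, adjusted p = 0.00139. Monocyte lineage genes rose as well, and of 10 members 3 rose and 0 fell (5 adjusted over the list alone, median 0.57, adjusted p = 5.78e-06, adjusted p = 0.0783 with an estimated correlation). Ly6c2 was at 0.50 ± 0.07, adjusted p = 0.000396. Cebpb (-0.59 ± 0.10, adjusted p = 0.00170) and the lactate dehydrogenase gene Ldhb (-0.77 ± 0.13, adjusted p = 0.00159) fell. For the cell cycle, of 20 members 0 rose and 2 fell (5 adjusted over the list alone, median -0.10, adjusted p = 0.000792, adjusted p = 0.454 with an estimated correlation). For mitochondrially encoded genes, of 13 members 0 rose and 5 fell (8 adjusted over the list alone, median -0.20, adjusted p = 6.59e-09, adjusted p = 0.0641 with an estimated correlation). The 29 named genes called had groups without overlap, and 1652 genes in all did (19.7%, chance 10%). DESeq2 gave no adjusted p for H2-Q6, Lipg, Tap1 and Oasl2. Counts were 55, 48 and 48 without IL4c mice 1, 2 and 3, and 264 without KP mouse 3. They were 39, 45 and 55 without naive mice 1, 2 and 3. Of 29 named genes called, 10 were called under every alternative, and 12 were lost without naive mouse 1.

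Some genes were called in both KP and IL4c mice. Genes called in the same direction against naive mice numbered 23 in progenitor-like, 66 in monocyte-like and 25 in neutrophil-like cells, and 14, 18 and 4 went opposite ways. If calls were independent, 2.86, 11 and 2.61 genes would rise in both, 1.02, 9.88 and 0.859 would fall in both and 3.62, 20.9 and 3.78 would oppose, where 15, 34 and 17 rose in both and 8, 32 and 8 fell in both. Both lists share the naive mice, which alone correlates the fold changes. Their correlation was 0.363, 0.232 and 0.323, below the means of 0.572, 0.509 and 0.599 in 20 simulations without any group effect. Covariances (0.0556, 0.0687 and 0.0861) exceeded the highest simulated ones (0.0388, 0.0347 and 0.0559), so how much of the overlap the naive mice bring stays open. DESeq2 numbers are listed below. Compared directly, IL4c and KP differed in 751 genes in progenitor-like cells (342 higher in IL4c), in 2990 in monocyte-like (1504) and in 454 in neutrophil-like cells (262). Il4ra was lower in IL4c than KP monocyte-like cells, at 17.4 ± 3.76 CPM against 39.7 ± 10.6 CPM (log2 -1.19 ± 0.26, adjusted p = 0.00790). Without IL4c mice 1, 2 and 3 these counts were 474, 451 and 468 in progenitor-like, 1639, 1777 and 1742 in monocyte-like and 220, 268 and 251 in neutrophil-like cells. Without KP mice 1 and 2 they were 1818 and 4571 in monocyte-like and 272 and 776 in neutrophil-like cells. DESeq2 called 481 in progenitor-like cells, and the 6 compared libraries gave 1806 in monocyte-like cells.

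Class shares were taken over bone marrow cells outside both neutrophil classes, because sorted neutrophils were added back. Against the 1 part to 10 parts that the labels state, these classes held 39.2% to 41.8% of naive, 49.7% to 63.5% of KP and 48.2% to 54.7% of IL4c cells. In KP mice monocyte-like cells made up 55.6% ± 2.84 against 40.2% ± 1.59 in naive mice, a difference of 15.4 percentage points. That difference was 6.10 with doublets kept, 5.35 under the stricter filter, 0.304 at resolution 0.5 and 0.0131 as a share of all cells. CD8 T-like cells (4.70% ± 1.46 against 8.76% ± 2.69), basophil-like (3.07% ± 0.934 against 4.91% ± 0.366), plasmacytoid dendritic-like (1.34% ± 0.604 against 4.06% ± 1.36), B-like (0.406% ± 0.155 against 1.80% ± 0.343), plasma-like (0.254% ± 0.160 against 0.917% ± 0.128) and stem and multipotent progenitor-like cells (3.03% ± 1.01 against 4.6% ± 0.280) were lower in 3 of 3 KP mice. In IL4c mice, monocyte-like cells (25.1% ± 5.14 against 40.2% ± 1.59), CD8 T-like (4.09% ± 0.716 against 8.76% ± 2.69), nonclassical monocyte-like (0.287% ± 0.255 against 6.56% ± 2.61) and plasma-like cells (0.565% ± 0.153 against 0.917% ± 0.128) were lower in 3 of 3. The CD8 T-like fall in IL4c rests on leaving cytotoxic lymphocyte cluster 16 unnamed. With it counted in, the share was 17.2% ± 9.94 against 9.06% ± 2.92, and mice overlapped. Basophil-like (6.62% ± 1.17 against 4.91% ± 0.366), erythroid-like (3.33% ± 0.227 against 1.99% ± 0.536), monocyte progenitor-like (16% ± 1.52 against 11.3% ± 1.21) and stem and multipotent progenitor-like cells (6.72% ± 1.69 against 4.6% ± 0.280) were higher in 3 of 3 IL4c mice. Granulocyte-monocyte progenitor-like shares overlapped (9.97% ± 3.02 against 6.56% ± 1.81 for KP, and 8.68% ± 1.48 for IL4c). Groups did not overlap in 7 of 12 classes for KP and 8 of 12 for IL4c, against 10% by chance. No share can pass, with an exact two-sided permutation p of 0.10 at the least (smallest adjusted p 0.171 for KP and 0.150 for IL4c). As shares of all cells, 4 of 12 classes did not overlap for IL4c, and the monocyte progenitor-like difference of 4.64 points was -0.142 at resolution 2.0.

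**Figure D4:**
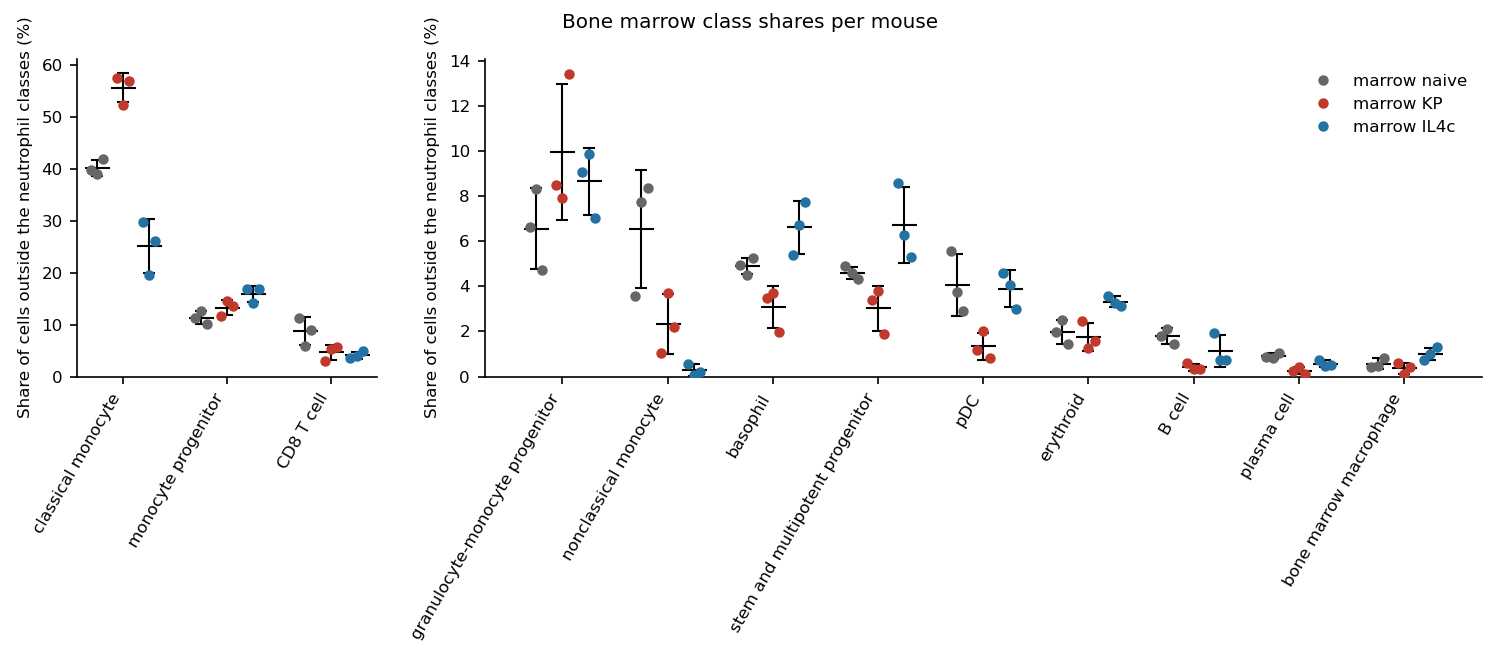
Percent of bone marrow cells outside the neutrophil classes (y axis) in each class (x axis), 1 dot per mouse with mean and SD of 3 mice, for naive, KP and IL4c mice, with the 3 most abundant classes on the left and 9 others on the right. Monocyte-like cells average 55.6% in KP, 40.2% in naive and 25.1% in IL4c mice.

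Basophil-like cells held most Il4 UMIs in bone marrow, 81 of 90 in IL4c, 58 of 74 in KP and 96 of 99 in naive mice. An Il4 UMI was found in 22.6% of 292 IL4c (exact 95% interval 17.9 to 27.8), 44.0% of 84 KP (33.2 to 55.3) and 34.4% of 221 naive basophil-like cells (28.2 to 41.1). Monocyte-like cells, which should lack Il4, gave 1 of 1145, 0 of 1530 and 0 of 1812 cells, where 0 allows up to 0.196% and 0.166% (1-sided 95%). Median UMIs per cell were 4992, 7210 and 3804 in basophil-like and 7861, 12650 and 5679 in monocyte-like cells. Thinned to 2000 UMIs per cell the basophil-like shares were 13.4%, 19.1% and 15.8% (intervals 9.48 to 18.1, 11.3 to 29.1 and 10.9 to 22). All intervals pool 3 mice, omit spread between mice and do not rank groups. Il13 had 3, 0 and 2 UMIs in IL4c, KP and naive bone marrow. In lung myeloid libraries Il13 had 54 UMIs in KO, all in ILC2-like cells, and 54 in WT, 50 of them in ILC2-like cells, while Il4 had 24 and 4. In T cell libraries Il13 had 42 UMIs in KO and 331 in WT, 274 of the latter in 15 CD4 T-like and 51 in 2 macrophage-like cells, and Il4 had 16 and 28.

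**Figure D5:**
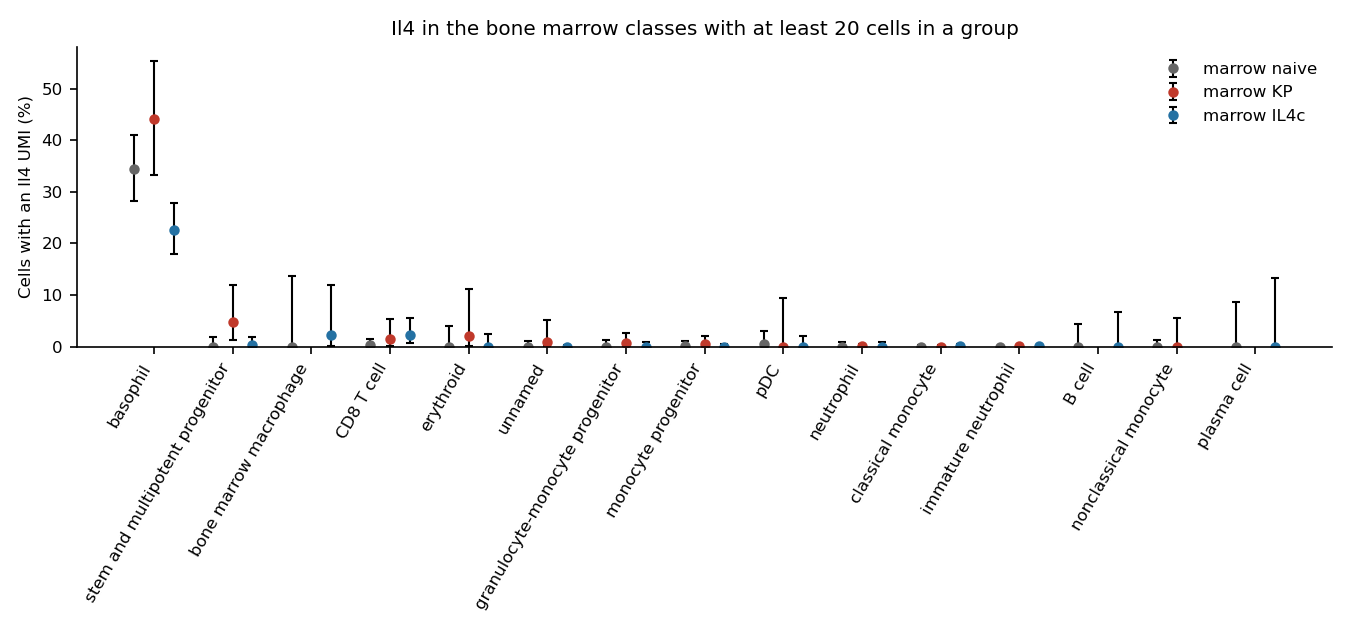
Percent of cells with an Il4 UMI (y axis) in each bone marrow class with at least 20 cells in a group (x axis), with exact 95% binomial intervals, for naive, KP and IL4c mice pooled by group. Basophil-like cells lie at 22.6% to 44.0%, above every other class drawn.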

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

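Every test of this part but the removal of the length trend was chosen only after the result was seen. The bounds for progenitor-like cells and free RNA in 5 classes were set after a first form of the test had given its value.

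An unnamed bone marrow cluster, which no comparison used, held 541 IL4c, 1 KP and 14 naive cells (6.10% of IL4c and 0.176% of naive cells), with 48, 287 and 206 cells in the IL4c mice. Its top genes, Gzma, Ccl5, Cd3d, Klre1, Eomes and Il2rb, are those of cytotoxic lymphocytes. Gzma stood at 0.0882 to 0.735 UMIs per cell in 10 other IL4c classes and at most 0.000409 in the same naive classes, and RNA of such lymphocytes in other droplets may be its source. In immature neutrophil-like cells the 20 transcripts most abundant in these and CD8 T-like cells, among those scarce in naive immature neutrophil-like cells, had an excess over naive cells of a median 0.360% of their source level (0.214% to 1.11%), a ratio of 0.780 to that of Gzma. Against own expression in 8 non-lymphoid classes, Gzma UMIs per cell differed only 2.19-fold between them while median depths differed 6.54-fold. In progenitor-like cells, at 4.55 times the median of the others, 174 of 252 Gzma UMIs lay in 8 of 389 cells, 7 of them with a T cell UMI. Without these 8 cells, picked by their Gzma in this class alone, the level was 0.205 UMIs per cell (0.109 to 0.239 in the other classes), which excludes nothing, so own expression there stays open.

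Ribosomal protein genes had medians above 0 in 3 classes of KP bone marrow, at 0.21, 0.12 and 0.26 (log2) in progenitor-, monocyte- and neutrophil-like cells, with 40 of 88, 34 of 88 and 19 of 80 rising and 1, 5 and 1 falling. The list was not called with an estimated correlation (adjusted p = 0.249, 0.466 and 0.518). IL4c medians were 0.025, 0.10 and 0.33, with 2, 6 and 0 rising, so in monocyte- and neutrophil-like cells the median shift is not particular to KP. With a trend of fold change on transcript length removed, 100.0%, 158% and 68.0% of the median stayed, and 38, 43 and 14 genes rose. This argues against that trend as the whole cause. Among ribosomal protein genes fold change fell with length (Spearman -0.44, -0.29 and -0.48), so length stays open. Depth stays open, because KP libraries held more UMIs and were a lane of their own. No biological explanation was tested.

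Neutrophil granule transcripts were higher in KP monocyte-like cells. RNA of neutrophils in these droplets could bring such transcripts at equal shares of their level in immature neutrophil-like cells, but the excess ran from 0.492% (Camp) to 75.3% (Chil3), a ratio of 153. Naive monocyte-like cells already hold Chil3 (20.8 UMIs per cell), and without it the highest was 7.99% (Cd177), a ratio of 16.2. The low end is depth, since Camp rose 2.22-fold per cell where total UMIs rose 2.15-fold. With naive levels scaled to KP depth, shares of -1.27% (Cebpe) to 65.3% (Chil3) argue against equal shares, not this source. Of mature neutrophil-like cells, whose Retnlg stood at 224.7 UMIs per cell, its excess allows 0.551%. Free RNA at 1 level in every droplet stays open for part of the S100a8 excess (111.8 UMIs per monocyte-like cell). In 5 other classes the excess was 7.36% (11 B-like cells) to 54.7% of that. Basophil-, CD8 T-, erythroid- and plasmacytoid dendritic-like cells held 22.7, 53.0, 58.2 and 61.2 UMIs per cell in excess. S100a8 UMIs per monocyte-like cell were 142, 43.9 and 170.4 in KP mice 1, 2 and 3, and a change made by the tumor in the monocytes themselves is untested.

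Of the other results, 2 are unnamed lung myeloid clusters, the first with Gpnmb, Cd63 and AY036118 on top at 4.23% of KO and 0.367% of WT cells (25, 71 and 16 against 2, 5 and 11 cells, untested), and the second with Gzmc, Xcl1 and Cd160 on top at 1.12% and 0.973% (10, 8 and 21 against 9, 13 and 21, untested). The rest are named genes called in opposite directions in 2 classes of the same mice, differences that were not tested. In KP, Lgals9 was at 0.55 in progenitor-like, -0.58 in monocyte-like and 0.63 in neutrophil-like cells (adjusted p = 0.0225, 0.0313 and 0.0471, differences 1.13 and -1.22). The progenitor call was lost without naive mouse 1 (0.150) or 3 (0.0847), with DESeq2 (0.0693), 6 libraries (0.0532) and thinned counts (0.0983). The monocyte call of Lgals9 was lost without KP mouse 1 (0.0874) or 3 (0.0548) or naive mouse 1 (0.0630), 2 (0.119) or 3 (0.0854) and with doublets kept (0.0518). Ngp was at -0.41 in progenitor-like and 1.35 in neutrophil-like cells (adjusted p = 0.00665 and 2.42e-05, difference -1.75), both calls lost at resolutions 0.5 (0.368 and 0.239) and 2.0 (0.311 and 0.124). Ctsd was at 0.64 in monocyte-like and -0.76 in neutrophil-like cells (adjusted p = 0.00541 and 0.00288, difference 1.40) and Egr1 at 3.29 and -1.28 (0.00317 and 0.00172, difference 4.57), each called under every alternative. In IL4c, Irf8 was at 2.57 in progenitor-like and -0.41 in monocyte-like cells (adjusted p = 0.000289 and 0.0324, difference 2.98). The former was lost with doublets kept (0.462), the latter without any IL4c or naive mouse or KP mouse 1, with doublets kept and at resolution 2.0 (0.0518 to 0.166). Of all genes called in both classes, 12 of 365 (progenitor and monocyte), 6 of 126 (progenitor and neutrophil) and 34 of 266 (monocyte and neutrophil) went opposite ways with no overlap of groups in KP, and 1 of 18, 0 of 15 and 0 of 13 in IL4c.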

How the results depend on the processing

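Thinning of KP counts to naive depth, the alveolar class without 1 cluster, cluster 16 counted as CD8 T-like, the sums over other classes (those with a value under every setting) and the counts over other splits were chosen after the results were seen. Of 274 called named genes, 147 were called under every alternative and 186 under every alternative that kept all mice. Named genes gave 10961 alternative values, of which 9927 kept direction and side of the threshold, 647 fell short of it, 385 passed it and 2 reversed. Both reversals were Mpo in KP monocyte-like cells, at -0.068 with doublets kept and -0.022 at resolution 0.5 (adjusted p = 0.748 and 0.921, log2). Among genes named after their values were seen, 2670 of 3136 values kept side and direction and Cd74 reversed, at -1.15 in IL4c monocyte progenitor-like cells at resolution 2.0 (adjusted p = 0.410). RLE size factors moved no count of genes by more than 1.5 times. For every change below the cause was not tested, except that fewer libraries, fewer genes tested or fewer cells are part of the setting itself.

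Counts of genes called that moved by more than 1.5 times, in the order progenitor-, monocyte- and neutrophil-like, were as follows. With the 6 libraries compared, KP gave 496 and 1267, IL4c 314, 1286 and 259, IL4c against KP 1806 in monocyte-like cells, and other IL4c classes 1595. With DESeq2, progenitor-like cells gave 450 for KP and 481 for IL4c against KP, other lung classes 140, and genes shared by KP and IL4c 100 alike and 28 opposite in monocyte-like cells and 2 opposite in neutrophil-like cells. With no low-count filter IL4c gave 177, 461 and 135 and other IL4c classes 1153, and lung gave 209 (CD8 T-like), 172 (CD4 T-like), 43 (macrophage-like), 63 (monocyte-like) and 730 (other). A replicate block gave 137, 111, 0 and 10 in these 4 lung classes, although in 13 pairings no replicate numbers paired the libraries (correlations from -0.116 to 0.289). Doublets kept gave 384 for IL4c monocyte-like and 1 for lung macrophage-like cells. Resolution 0.5 gave 371 and 0 for these, resolution 2.0 gave 0 for lung macrophage-like and 1 for lung monocyte-like cells, and the stricter filter 0 and 5. Thinned KP counts gave 91 for IL4c neutrophil-like cells.

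Leaving out each mouse in turn gave the ranges below, and the report names the mice where these counts moved by more than 1.5 times. For progenitor-like cells these were 329 to 1047 (KP), 39 to 264 (IL4c) and 451 to 995 (IL4c against KP). For monocyte-like cells they were 909 to 4004, 35 to 673 and 1639 to 4571, and for neutrophil-like cells 301 to 836, 19 to 167 and 220 to 776. Lung gave 9 to 63 (CD8 T-like), 16 to 69 (CD4 T-like), 0 to 6 (macrophage-like) and 1 to 6 (monocyte-like). Other lung classes gave 178 (without KO mouse 3) to 238 against 268. Other KP classes gave 2604 (without naive mouse 2) to 5826 against 4509, with 2846 without naive mouse 1. Other IL4c classes gave 231 (without naive mouse 1) to 1394 (without KP mouse 3) against 556, with 249 and 289 without IL4c mice 2 and 3 and 316 and 253 without naive mice 2 and 3. Classes free of overlap ranged from 1 to 4 in myeloid and 2 to 5 in T cell libraries. Gene lists called with an estimated correlation numbered 0 in all main comparisons but CD4 T-like cells (1), IL4c progenitor-like (2) and IL4c monocyte-like cells (6).

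Differences in class shares, in percentage points, moved as follows. Monocyte-like cells in KP gave 6.10 with doublets kept, 5.35 under the stricter filter, 0.304 at resolution 0.5 and 0.0131 of all cells. Monocyte progenitor-like cells in KP gave -0.336, -1.19, -0.748 and -0.959 under the same settings and -4.59 at resolution 2.0, and in IL4c -0.142 at resolution 2.0, a reversal, and 0.991 of all cells. Under the stricter filter B-like cells gave -0.775 (KP) and -0.0301 (IL4c), erythroid-like -0.799 (KP), CD8 T-like -1.37 (IL4c), bone marrow macrophage-like 0 (IL4c), macrophage-like cells of T cell libraries 0.0831, and 0 myeloid classes were free of overlap. At resolution 0.5 CD8 T-like cells gave 0 in KP and IL4c, as no cluster held that name, and with cluster 16 counted as CD8 T-like the IL4c difference reversed to 8.09 (-4.67 before). At resolution 0.5 plasmacytoid dendritic-like cells gave -5.26 (KP). Stem and multipotent progenitor-like cells in IL4c gave 0.763 with doublets kept. As shares of all cells, KP gave -0.903 (B-like), 0.370 (granulocyte-monocyte progenitor-like) and -0.431 (plasma-like), and IL4c 0.266 (basophil-like), 0.144 (bone marrow macrophage-like), 0.426 (erythroid-like), 0.264 (granulocyte-monocyte progenitor-like), -3.76 (nonclassical monocyte-like) and 0.535 (stem and multipotent progenitor-like), with 4 classes free of overlap.

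The 6 mice of a comparison make 10 splits, too few for a share under 0.05. Other splits called 0 genes at most in every bone marrow comparison, where only 1 split, the real one, reached the real count. Other splits mix mice of both groups, so any difference between the groups widens the spread within each part and lowers the count. A count of 0 there therefore excludes nothing. Only the real split also divides the lanes. In lung the highest other split called 24 genes in CD8 T-like (real 14, reached by 2 splits), 4 in CD4 T-like (real 47), 17 in macrophage-like (real 2, reached by 5), 4 in monocyte-like (real 2, reached by 4) and 15 in other classes (real 268). In several comparisons other splits called as many gene lists at the preset correlation as the real split, or more. In lung 4, 6, 12 and 12 lists were called in macrophage-, monocyte-, CD8 T- and CD4 T-like cells, and the highest other split called 10, 8, 12 and 9 (7, 4, 2 and 1 splits reached the real count). For KP in progenitor-, monocyte- and neutrophil-like cells they numbered 5, 11 and 8 against 5, 8 and 10 (5, 1 and 2 splits), and for IL4c 6, 15 and 7 against 4, 13 and 10 (1, 1 and 4 splits).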

Other observations

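The genes named in this part and the alveolar class without 1 cluster were chosen after their values were seen, except the genes that both hypothesis tests measured, which were listed before. In KO lung, 86 genes were called in alveolar macrophage-like cells (26 higher). Plac8 (-3.63 ± 0.38, adjusted p = 9.09e-07), Ifitm3 (-3.54 ± 0.37, adjusted p = 9.09e-07) and S100a6 (-1.11 ± 0.11, adjusted p = 6.04e-07) fell. A cluster with 48 WT cells and 1 KO cell lay in this class, and without it 42 genes were called (21 higher), with Plac8 at -1.88 (adjusted p = 0.0232), Ifitm3 at -1.40 (0.00475) and S100a6 at -0.76 (0.00122). In NK-like cells 119 genes were called (29 higher), and proliferation genes Mki67 (-1.53 ± 0.28, adjusted p = 0.00110) and Birc5 (-2.58 ± 0.42, adjusted p = 0.000224) fell, without an adjusted p from DESeq2. Type 2 conventional dendritic-like cells had 32 calls (12 higher), with Mfge8 (-1.57 ± 0.23, adjusted p = 0.00452) and Fabp5 (-1.09 ± 0.13, adjusted p = 0.00199) lower. Of this class, 39.3% (KO) and 55.9% (WT) lay in cluster 10 and 55.1% and 32.8% in cluster 13. Type 1 dendritic-like cells had 14 calls (6 higher), with Trf at 1.2 ± 0.15, adjusted p = 0.00161. Gamma-delta T-like cells had 12 (5 higher), with Ckb at 1.02 ± 0.19, adjusted p = 0.000962. Nonclassical monocyte-like cells had 3, among them Ifi27l2a (-0.75 ± 0.12, adjusted p = 0.00624), AY036118 (1.16 ± 0.15, adjusted p = 0.000245) and Gm42418 (0.50 ± 0.09, adjusted p = 0.0153). The last 2 were lost with DESeq2 (adjusted p = 0.426 each), and Gm42418 also without WT mouse 2 (0.0517) or 3 (0.124) and with doublets kept (0.181). In T cell libraries, regulatory T-like cells had 2 calls (Trbv20 and AY036118), monocyte-like 1 (Ifi27l2a) and macrophage-like 3 (Alox15, Gzma and Ly6a), each lost without KO mouse 1 or 3 (adjusted p from 0.0509 to 0.358). For the type 2 helper list in regulatory T-like cells, of 5 members 0 rose and 0 fell (0 adjusted over the list alone, median 0.07, adjusted p = 0.773).

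In bone marrow, immature neutrophil-like cells had 2830 genes called in KP (1480 higher) and 465 in IL4c (363 higher). Clusters 18 and 32 of this class held 489 and 117 KP cells, 413 and 98 of them from KP mouse 3, and 0 naive cells. S100a6 rose in KP (2.59 ± 0.17, adjusted p = 1.77e-06), and H2-Q7 (4.23 ± 0.34, adjusted p = 2.49e-05), H2-K1 (2.02 ± 0.18, adjusted p = 6.28e-05) and Tap1 (1.47 ± 0.08, adjusted p = 8.47e-07) rose in IL4c. Monocyte progenitor-like cells had 1679 calls in KP (828 higher), with Vcan (3.23 ± 0.26, adjusted p = 6.49e-07) up, and 91 in IL4c (68 higher), with H2-Q7 up (2.53 ± 0.27, adjusted p = 0.000178). CD8 T-like cells had 162 calls in KP (89 higher), with the chemokine Xcl1 down (-2.74 ± 0.43, adjusted p = 0.000933), and 253 in IL4c (124 higher). There Gzma (5.54 ± 0.40, adjusted p = 1.49e-08) rose and naive T cell genes Lef1 (-1.82 ± 0.18, adjusted p = 2.58e-06) and S1pr1 (-2.09 ± 0.29, adjusted p = 0.000131) fell. These bone marrow genes were called under every alternative that gave a value (resolution 0.5 left no CD8 T-like class).

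Naive mouse 2 had 5.31 CPM of Xist against 785 and 746 in naive mice 1 and 3, without Ddx3y. A single X chromosome may explain this. The test, over 6 genes that escape X inactivation, gave a median of -0.334 (log2) against mice 1 and 3, with 5 of 6 lower, against 0.010 for 199 other X-linked genes, and 0 of 10000 random lists lay as low.

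In KP, Fkbp5 rose in monocyte-like (2.99), neutrophil-like (1.96) and CD8 T-like cells (2.77), as did Tsc22d3 (0.79, 0.67 and 1.81), both induced by glucocorticoids. If a glucocorticoid response were the cause, further such genes could be higher too. Their medians were 0.19, 0.15 and 0.70 (lowest 0.151), with 9, 3 and 2 genes measured, of which Mt1, Errfi1, Irs2 and Glul rose and Sesn1 fell in monocyte-like cells, and Glul did not pass in the others (adjusted p = 0.0670 and 0.130). The question stays open.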
